A study of Zea mays with 15 samples.

How the data were processed

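Total RNA from maize roots was measured on 15 NimbleGen 1-colour arrays, 3 for each of 5 groups, and each array held RNA pooled from the roots of 6 plants. The groups were a nitrogen-free control, nitrate, water-extractable humic substances (WEHS) and both additions together, all after 4 h, and both additions together after 8 h. There was no 8 h control. The labels state that the treatments were repeated 3 times, and they number the replicates from 1 to 3 in the sample titles. The sample descriptions instead give the same ordinal to all replicates of a group, so the title numbers were used, and the replicate block rests on them.

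The deposited array files give 1 intensity per probe on a linear scale, which the authors had already normalized between arrays. The only tool that the submitters name is RMA, without a version. Of 140663 probes, 139000 belong to 59756 transcripts of 39219 genes and 1663 are random sequences. All arrays have nearly the same distribution of values, with median intensities between 549.95 and 550.03, so quantile normalization was taken as done. WEHS replicate 3 stands apart, with 49 probes at a maximum of 51143.46, against 59379.95 on the other arrays. Its random probes correlated with those of other arrays at 0.606 to 0.699, where the lowest value of any other pair was 0.726. The gibberellin list calls below end without it, among other arrays. The deposited value table holds the same intensities (largest difference 0), and the mismatch column is empty of signal and was not used. No background correction or further normalization was applied.

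Intensities were transformed to log2, and the probes of a transcript were combined by median polish. A transcript was tested if its value exceeded the 95th percentile of the random probes on at least 3 of the 15 arrays. That percentile lay between 229.3 and 359.2 intensity units, and from 58.4 to 66.5% of the transcript probes of an array lay above it. This left 42976 transcripts (71.9%) of 29924 genes, and 16780 transcripts were not tested. For arrays, the number of replicates limits the precision, and the median 95% interval of a difference of 2 groups reached 0.42 log2 units to either side.

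The 5 group means were fitted in limma 3.58.1 (R 4.3.3) to all 15 arrays at once, with 10 residual and 2.95 prior degrees of freedom and a prior SD of 0.218 log2 units. The 8 contrasts of the groups were tested with moderated two-sided tests, and p was adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. "Rose", "fell" and "changed" are used of transcripts past that threshold, and every adjusted p given for a transcript is from this fit. The fit was tested on simulated data with known changes.

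Gene names came only from the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, of which no coordinates were used. Of the array's genes, 18171 matched 1 RefSeq gene, 519 matched several and 20529 matched none, and 2510 carried an informative symbol. Of these, 2061 had a tested transcript. The list of symbols treated as uninformative was extended once after the first lists of names had been seen. The table has no gene descriptions, so 32 gene lists fixed beforehand were matched by symbol alone, and 28 of them had at least 3 measured genes. A list took the brightest transcript of each gene. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 224 tests, and beside it with an estimated correlation and with fry. A symbol may belong to another kind of gene, and 36 list members did by inspection of the symbols.

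The genes named follow a rule fixed in advance. For each comparison these are the 8 largest rises and the 8 largest falls among named transcripts that passed with groups that do not overlap, 1 per gene, up to 4 members of each list with the smallest p, all measured genes of nitrate transport and reduction, and at most 2 rises and 2 falls without a name, by identifier. Genes named outside the rule are marked as chosen after their values were seen.

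The comparisons, the lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives were normexp background correction with offset 0, cyclic loess normalization, the mean of the probes, no filter, a filter that asks for all 15 arrays, the replicate number as a block, only the arrays of the groups compared, a trended and robust spread estimate, array weights, an adjusted p of 0.01, an added minimum of 1 log2 unit, all transcripts of a gene in the lists, and leaving out each array in turn. Added after the data had been seen were an offset of 50, the first axis of the random probes as a covariate, lists without members of another kind of gene and lists with added members. The replicate number was not used as a block in the fit reported, as planned. Deviations from the group means correlated above 0.1 for every equally numbered pair in 1 of 7 pairs of groups, WEHS against control (0.36 to 0.57).

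The 12 arrays of 4 h lay on places 1 to 12 of a slide in the order control, nitrate, WEHS and both, and were read in 1 scan. The 8 h arrays carry the same slide number and places 1 to 3, but their image names give another scan, with no other group. Since the control arrays hold those places in the first scan, the 8 h arrays must be another hybridisation or slide. The labels do not say which, and scan stands below for any of these. Scan and group therefore cannot be told apart for the 8 h arrays, and place and group cannot within 4 h, so neither could be a term of the fit.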

Results

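The data are transcript levels in roots of 5-day-old maize plants (cultivar PR33T56) kept in hydroponics. Plants received a nitrogen-free solution (control), 0.5 mM calcium nitrate, 5 mg per litre of organic carbon as water-extractable humic substances (WEHS, the soluble part of humified organic matter), or both, for 4 h. Plants given both were also sampled at 8 h. Each of the 5 groups has 3 arrays. Values are log2 intensities of transcripts, and 42976 of 59756 transcripts were tested. Between arrays of a group, values correlated across transcripts at 0.938 to 0.992, and between arrays of different groups at 0.901 to 0.988. The differences between groups accounted for 40.2% of the variance, where 28.6% arises by chance.

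**Figure D1:**
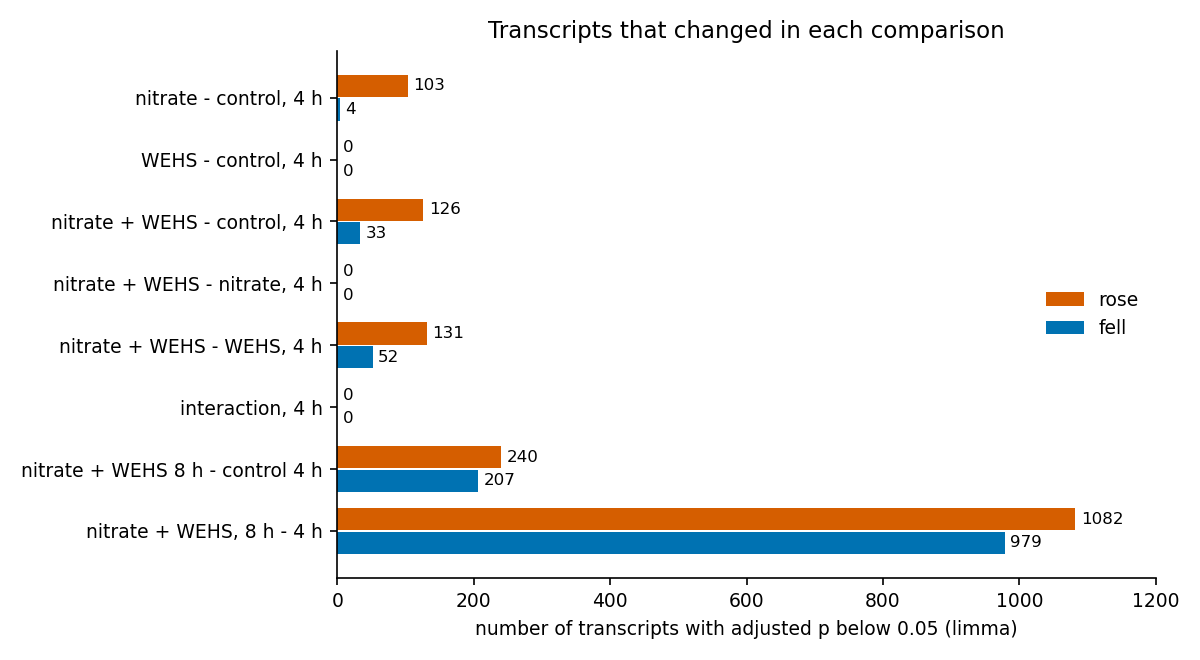
Number of transcripts (horizontal axis) that rose or fell past the threshold of limma in each of the 8 comparisons, labelled on the bars. The comparison of 8 h with 4 h has 1082 rises and 979 falls, and the 2 comparisons that add WEHS at 4 h and the interaction have 0.

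The first comparison asked which root transcripts respond to nitrate within 4 h in nitrogen-starved plants. Transcripts for the reduction of nitrite and its siroheme cofactor (NIR, sum1), for ammonium assimilation (gln1, fgs1) and for the supply of reductant (fnr1, pgd3) rose. So did the regulators TAZ1, GLK52, HB34 and LOB14, the hemoglobin Hb2 and the cytokinin oxidase CKX6. No transcript with a gene name fell. Of 42976 transcripts, 103 rose (79 genes, 16 of them named) and 4 fell. In all 107 the values of the 2 groups did not overlap, which was true of 8.2% of all transcripts and is true of 10% by chance. With 1 array left out there were 70 to 117 rises and 1 to 8 falls, and a fit to the 2 groups alone gave 35 and 0. With simulated changes in this comparison, 46% of 50 transcripts changed 2-fold and 96% of 50 changed 4-fold were recovered, with 8 false calls among 42976.

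The largest named rise was in sum1 (GRMZM2G105604), from 6.79 ± 1.23 in control to 11.49 ± 0.44 with nitrate (log2 intensity, SD, n = 3). Its log2 change was 4.70 (SE 0.45, adjusted p = 0.000238). The gln1 gene GRMZM2G098290 rose in T03, 1 of its 2 transcripts, from 6.30 ± 0.33 to 10.19 ± 0.30 (SD, 3 arrays each). This was a change of 3.89 (SE 0.27, adjusted p = 1.32e-05). All 5 transcripts of NIR (GRMZM2G079381) rose. Its transcript T04 changed by 3.82 (SE 0.58, adjusted p = 0.0106), a call that the absence of either of 2 arrays ended, as it did for CKX6, and T05 by 3.06 (SE 0.39, adjusted p = 0.00233). TAZ1 (GRMZM2G004161) rose in all 5 of its transcripts, T05 by 3.51 (SE 0.24, adjusted p = 1.34e-05). On all control and WEHS arrays, gln1 T03, TAZ1 T05 and NIR T04 lay under the 95th percentile of the random probes. So did sum1, except on control replicate 1 (8.19). No background correction was applied, so the sizes and the ranking of these rises depend on the background, here and in the comparisons below. Hb2 rose by 2.90 (adjusted p = 2.08e-05), HB34 by 2.76 in 1 of its 2 transcripts (adjusted p = 6.7e-06), the pdh2 gene GRMZM2G043198 by 2.62 (adjusted p = 0.000936) and GLK52 by 2.60 (adjusted p = 3.95e-06). Ferredoxin-NADP reductase fnr1 went from 11.56 ± 0.16 to 13.96 ± 0.15 (SD), a change of 2.40 (SE 0.12, adjusted p = 1.12e-06). The 6-phosphogluconate dehydrogenase pgd3 rose by 1.34 (adjusted p = 0.000189), CKX6 by 1.23 (adjusted p = 0.00809), the terpene synthase TPS7 by 1.11 (adjusted p = 0.00483) and fgs1 by 0.78 (adjusted p = 0.00178). Outside the naming rule and chosen after their values were seen, LOB14 rose by 1.61 (adjusted p = 0.00178) and gpt by 0.79 (adjusted p = 0.0146). Without a name, GRMZM2G127909 rose by 4.15 (adjusted p = 3.76e-07) and GRMZM5G828229 by 3.20 (adjusted p = 0.00151), while GRMZM2G000932 fell by 1.77 (adjusted p = 0.00834) and GRMZM2G049695 fell by 1.53 (adjusted p = 0.0202), calls that ended without 1 array and without any of 5 arrays. The count of 4 falls was 7, 1 and 1 without control replicates 1, 2 and 3, 2 without nitrate replicate 1 or 3, 2 and 8 without joint replicates 1 and 2 at 4 h, and 2 without 8 h replicate 1 or 2 or WEHS replicate 2.

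**Figure D2:**
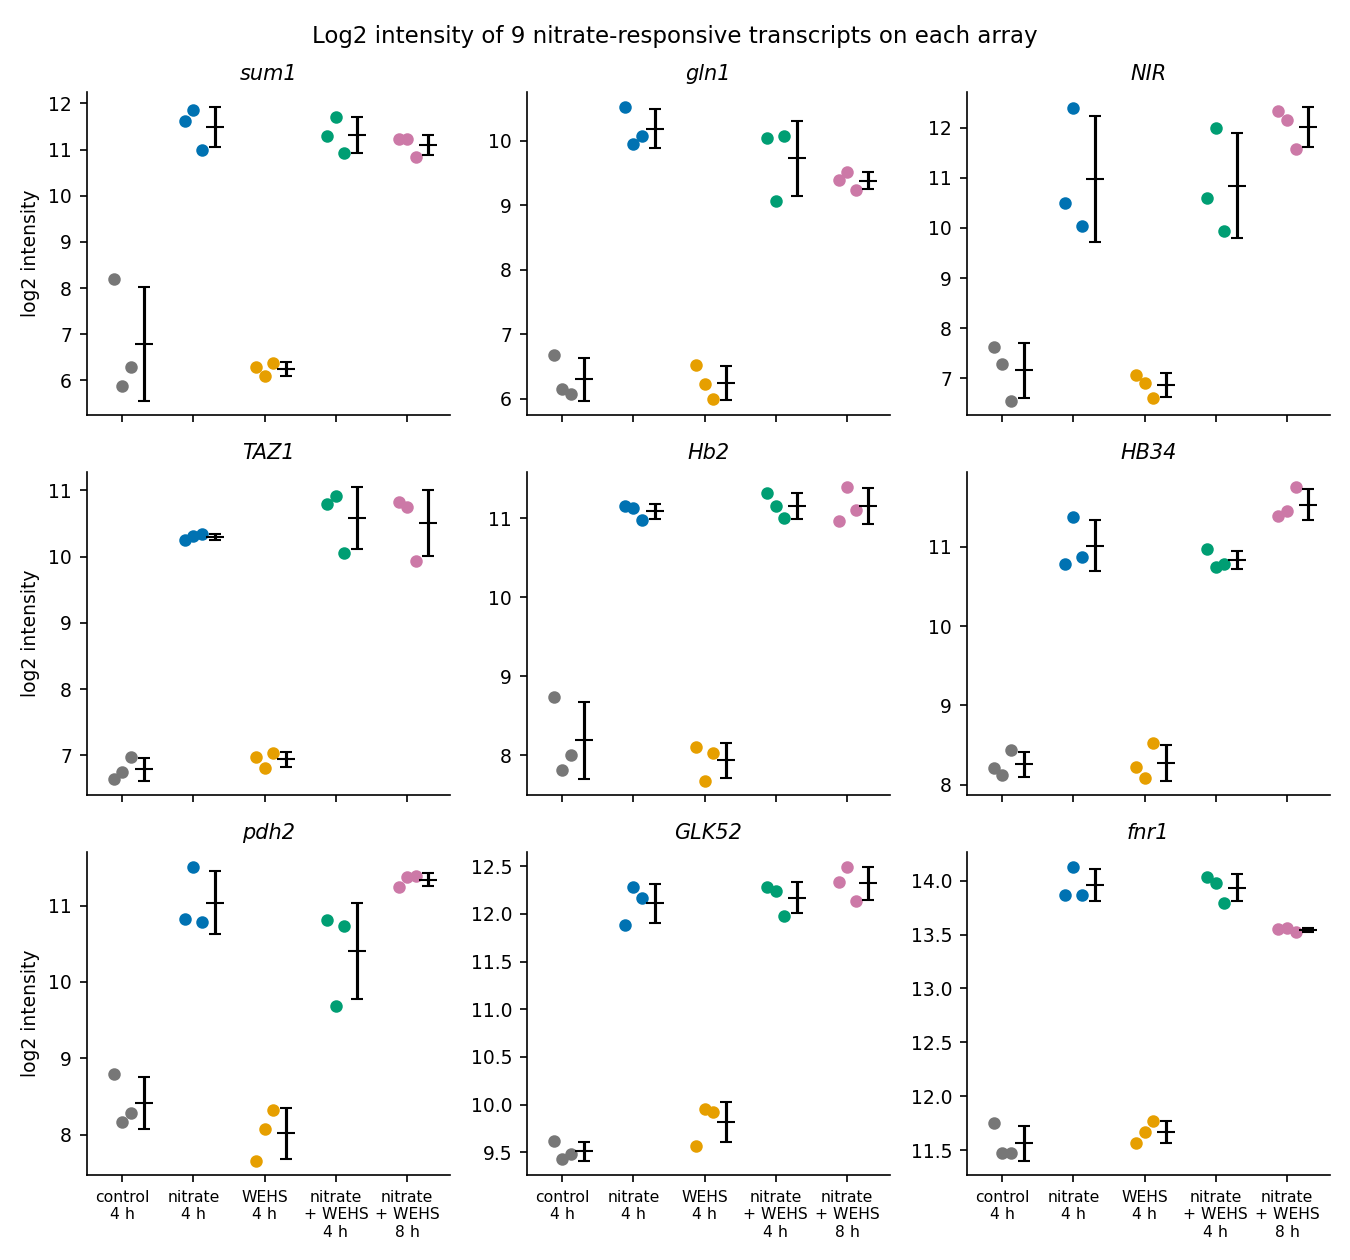
Log2 intensity (vertical axis) of 9 genes that rose with nitrate, in each of the 5 groups, with a dot per array and the mean ± SD of 3 arrays as a dash and bar. In sum1 the nitrate arrays average 11.49 and the control arrays 6.79, and in fnr1 13.96 and 11.56.

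The named nitrate transporters and nitrate reductases did not pass over all transcripts. The nitrate transporter nrt2.2 differed by 0.84 (adjusted p = 0.749), its partner NAR2.1 by 0.80 (adjusted p = 0.186) and NRT1.2 by 0.31 (adjusted p = 1). The reductase genes NNR1 and NAR differed by 1.87 (adjusted p = 0.206) and 3.82 (adjusted p = 0.128), and NAR had an SD of 2.29 among the control arrays. The 3 genes of nitrate transport, 0 of which passed over all transcripts, moved up as a list (camera, adjusted p = 0.00348, and adjusted p = 0.689 with an estimated correlation). Adjusted over the list alone, 2 of them passed, nrt2.2 and NAR2.1. Of 6 genes of the pentose phosphate pathway and ferredoxin, which include another pdh2 gene, GRMZM2G127798 (0.10, adjusted p = 1), 2 rose, and 3 adjusted over the list alone, fnr1, pgd3 and FDX6 (list adjusted p = 1.54e-07, and adjusted p = 0.207 with an estimated correlation). Of 17 cytokinin genes, 1 rose, and 4 adjusted over the list alone, CKX6, CKX8, CKX12 and RR4 (list adjusted p = 0.0431, and adjusted p = 0.873 with an estimated correlation). In the ammonium assimilation list, fgs1, gln3 and the brighter transcript T01 of the gln1 gene GRMZM2G098290, by 0.94, rose when adjusted over the list alone. The list itself did not pass (adjusted p = 0.343). Leaving out 1 array ended the call of nitrate transport for control replicate 1 (adjusted p = 0.0795) and nitrate replicate 2 (adjusted p = 0.0814). It ended that of cytokinin for control replicates 2 and 3 (adjusted p = 0.152 and 0.247), nitrate replicates 2 and 3 (adjusted p = 0.0653 and 0.146), WEHS replicates 2 and 3 (adjusted p = 0.0621 and 0.0613) and replicate 2 of the joint treatment at 4 h (adjusted p = 0.0513).

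The second comparison asked what WEHS alone does to root transcripts at 4 h. No gene passed in limma, and the smallest adjusted p was 1. At an unadjusted p below 0.05, 1066 transcripts (2.5%) differed, which is under the share of 0.05 that arises by chance. The differences of single genes that follow are therefore not calls. The an1 gene GRMZM2G081554 of gibberellin synthesis was 1.20 higher (SE 0.33, unadjusted p = 0.00314), asn3 1.01 higher (unadjusted p = 0.0244), Hsf17 0.55 higher (unadjusted p = 0.0132) and bronze-2 0.52 higher (unadjusted p = 0.00713). The nitrate transporter nrt2.2 was 0.53 higher (unadjusted p = 0.0763), and NNR1 differed by -0.66 (unadjusted p = 0.158). The 103 transcripts that nitrate raised had a median difference of 0.04 here, with 58 above and 45 below 0.

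All 4 gibberellin genes were higher with WEHS, 0 of them past the threshold over all transcripts and 1, an1, adjusted over the list alone. As a list they moved up (camera, adjusted p = 0.00348, and adjusted p = 0.359 with an estimated correlation), while fry, which tests the list by itself, gave an adjusted p of 0.193. The list call was lost without WEHS replicate 2 (adjusted p = 0.0587) or WEHS replicate 3 (adjusted p = 0.106).

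The third comparison asked which transcripts respond to nitrate and WEHS given together for 4 h. NIR, sum1, gln1, fgs1, fnr1 and pgd3 rose again, with TAZ1, HB34, GLK52, Hb2 and the cytokinin oxidases CKX6 and CKX8. Among the named genes that fell were psy2 of carotenoid synthesis and the regulators bZIP111 and bHLH172. In limma, 126 transcripts rose (101 genes, 17 named) and 33 fell (32 genes, 4 named), and in all of these the groups did not overlap, against 18.2% of all transcripts and 10% by chance. With 1 array left out there were 70 to 139 rises and 1 to 49 falls, and a fit to the 2 groups alone gave 26 and 4.

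With both additions, sum1 rose by 4.52 (SE 0.45, adjusted p = 0.000345), TAZ1 by 3.80 (adjusted p = 8.27e-06) and NIR T01 by 3.77 (SE 0.42, adjusted p = 0.000831). The gln1 transcript T03 rose by 3.43 (adjusted p = 4.7e-05) and Hb2 by 2.96 (adjusted p = 1.96e-05). GLK52 rose by 2.66 (adjusted p = 3.14e-06), HB34 by 2.59 (adjusted p = 1.26e-05) and fnr1 by 2.37 (adjusted p = 1.27e-06). Smaller rises were those of CKX8 by 1.45 (adjusted p = 0.0117), pgd3 by 1.21 (adjusted p = 0.000378), CKX6 by 1.14 (adjusted p = 0.0156), TPS7 by 1.04 (adjusted p = 0.00952) and fgs1 by 0.71 (adjusted p = 0.00409). bZIP111 fell by 1.64 (adjusted p = 0.0383), psy2 T03 fell by 1.28 (adjusted p = 0.0222) and bHLH172 fell by 0.74 (adjusted p = 0.0122). The number of arrays whose absence alone ended the call was 10 of 15 for bZIP111, 4 each for psy2, bHLH172 and CKX8, 3 for CKX6, 2 for TPS7, 12 for GRMZM2G077914 and 7 for GRMZM2G147446. Without a name, GRMZM2G127909 rose by 4.20 (adjusted p = 3.27e-07) and GRMZM2G474039 by 3.20 (adjusted p = 0.00276), while GRMZM2G147446 fell by 1.78 (adjusted p = 0.0327) and GRMZM2G077914 fell by 1.74 (adjusted p = 0.0482). NNR1 was 1.91 higher, which did not pass (adjusted p = 0.106), and nrt2.2 was 0.80 higher (adjusted p = 0.28).

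The cytokinin list moved up with both additions (adjusted p = 0.000549, and adjusted p = 0.359 with an estimated correlation), with 2 of 17 genes past the threshold and 4 adjusted over the list alone. So did pentose phosphate and ferredoxin (adjusted p = 0.000968, and adjusted p = 0.359 with an estimated correlation), in which fnr1 and pgd3 passed, and, adjusted over the list alone, FDX6 rose and FdI fell too. The ammonium assimilation list was not called, and its members went both ways when adjusted over the list alone. With both additions fgs1, gln3, GLN6 and gln1 rose, while Gln1-4 (by 1.10), AS (by 0.41) and gln1-3 (by 0.37) fell. Beside WEHS, fgs1 and gln1 rose and Gln1-4 and gln1-3 fell, and at 8 h fgs1, gln1, gln2 and gln3 rose and Gln1-4, gln1-3 and glu2 fell.

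The fourth comparison asked what WEHS adds where nitrate is present. No transcript changed in limma (smallest adjusted p 0.896). At an unadjusted p below 0.05, 1923 (4.5%) differed, under the share of 0.05 that arises by chance. No gene list passed with camera or with fry (smallest fry adjusted p 0.453). Among list members the ethylene response factors EREB203 and EREB65 differed by -0.58 (unadjusted p = 0.00315) and 1.74 (unadjusted p = 0.0128), the malate dehydrogenase mdh6 by 0.74 (unadjusted p = 0.0194), the expansin EXPB10 by -0.48 (unadjusted p = 0.0227) and ARF19 by -0.41 (unadjusted p = 0.0222). For nitrate transport, nrt2.2 differed by -0.04, NAR2.1 by -0.18 and NRT1.2 by -0.27, and NNR1 by 0.04.

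The fifth comparison asked what nitrate adds where WEHS is present. The nitrate reductases NAR and NNR1 rose, beside NIR, sum1, gln1, TAZ1, Hb2, fnr1 and pgd3. Among the named genes with a transcript that fell were dxs2, dxr and Hds1 of plastid isoprenoid synthesis, psy2 of carotenoid synthesis, CCD8 of carotenoid cleavage and an1 of gibberellin synthesis. This grouping was made after the falls were seen. No fixed list covers isoprenoid or carotenoid synthesis, and no enrichment was tested. In limma, 131 transcripts rose (102 genes, 21 named) and 52 fell (45 genes, 11 named), all with groups that did not overlap, against 18.9% of all transcripts and 10% by chance. With 1 array left out there were 64 to 172 rises and 11 to 162 falls, and a fit to the 2 groups alone gave 45 and 8.

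In this comparison sum1 rose by 5.06 (adjusted p = 0.000137), NAR by 4.56 (SE 0.82, adjusted p = 0.0319) and NIR T01 by 4.26 (adjusted p = 0.000304). TAZ1 rose by 3.65 (adjusted p = 1.12e-05), gln1 T03 by 3.48 (adjusted p = 3.41e-05) and Hb2 by 3.22 (adjusted p = 1.12e-05). GLB1 rose by 2.62 (adjusted p = 0.0416), NNR1 by 2.57 (adjusted p = 0.0232), fnr1 by 2.27 (adjusted p = 2.26e-06), pgd3 by 1.30 (adjusted p = 0.000212), TPS7 by 1.21 (adjusted p = 0.00237), CKX8 by 1.19 (adjusted p = 0.0386) and fgs1 by 0.62 (adjusted p = 0.0111). The an1 transcript T06 fell by 3.57 (adjusted p = 0.0164) and its brighter T01 fell by 2.32, from 13.49 ± 0.26 to 11.17 ± 0.23 (SD, adjusted p = 0.00661). dxs2 T01 fell by 3.28 (adjusted p = 0.042) and its brighter T02 fell by 3.14 (adjusted p = 0.00625), CCD8 fell by 2.15 (adjusted p = 0.0363), bZIP111 fell by 1.95 (adjusted p = 0.0111) and psy2 T02 fell by 1.90 (adjusted p = 0.011). dxr T02 fell by 1.88 (adjusted p = 0.0179), 1 of its 2 transcripts, cad fell by 1.34 (adjusted p = 0.0423) and Hds1 fell by 0.99 (adjusted p = 0.0485). Several of these calls lie near the threshold: the number of arrays whose absence alone ended the call was 12 of 15 for Hds1 and cad, 11 for dxs2 T01, 8 for CCD8, 5 for an1 T06 and 0 for its T01, 4 for dxr, 3 for psy2 and 2 for bZIP111. For the rises it was 11 for GLB1, 10 for CKX8, 9 for NAR, 4 for NNR1 and 3 for fgs1. Without a name, GRMZM2G071704 rose by 4.70 (adjusted p = 0.000733) and GRMZM2G127909 by 4.58 (adjusted p = 1.08e-07), while GRMZM2G000614 fell by 2.46 (adjusted p = 0.0021) and GRMZM2G116461 fell by 2.46 (adjusted p = 0.00858).

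**Figure D3:**
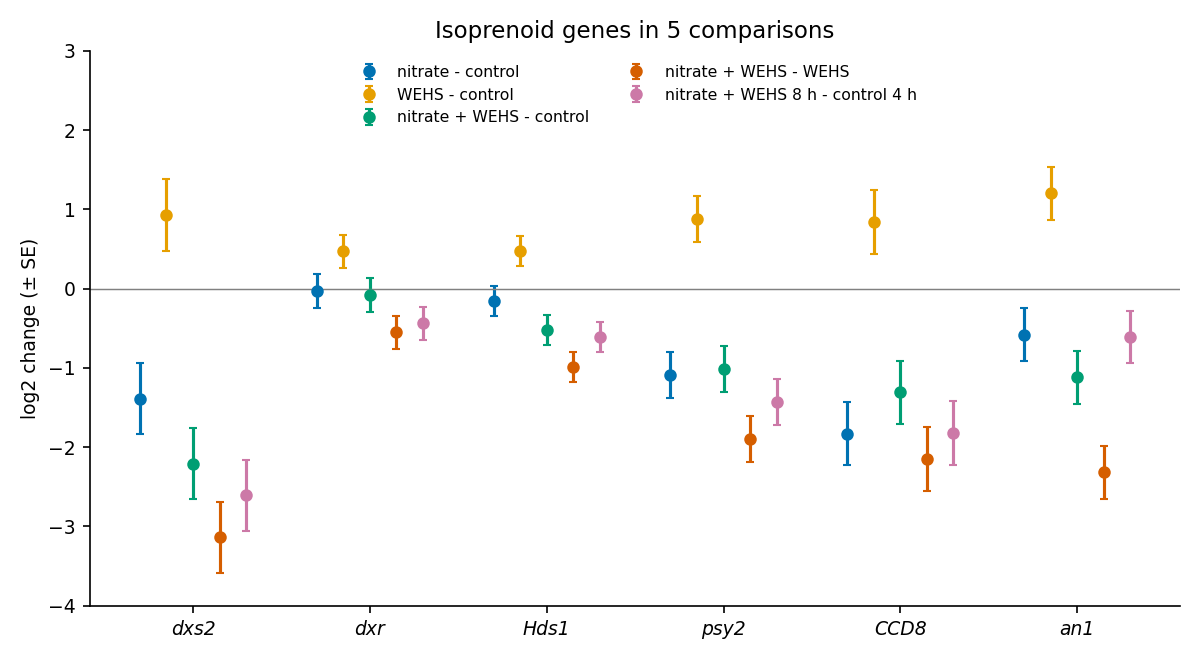
Log2 change ± SE (vertical axis) of dxs2, dxr, Hds1, psy2, CCD8 and an1, each by its brightest transcript, in 5 comparisons. In nitrate plus WEHS against WEHS they range from -3.14 for dxs2 to -0.55 for dxr, which did not pass in that transcript.

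Of the lists, pentose phosphate and ferredoxin moved up (adjusted p = 0.000549, and adjusted p = 0.359 with an estimated correlation; 2 of 6 genes passed, and 3 adjusted over the list alone). Cytokinin moved up (adjusted p = 0.0123, and adjusted p = 0.657 with an estimated correlation; 1 of 17 passed, and 2 adjusted over the list alone). Ribosomal proteins moved up with 23 of 27 genes above 0 and 0 past the threshold over all transcripts or adjusted over the list alone (list adjusted p = 0.0125, and adjusted p = 0.973 with an estimated correlation). The 4 gibberellin genes moved down (adjusted p = 0.0354, and adjusted p = 0.68 with an estimated correlation), and 1, an1, fell over all transcripts and adjusted over the list alone. Leaving out 1 array ended the gibberellin call for control replicate 2 (adjusted p = 0.0553), WEHS replicates 2 and 3 (adjusted p = 0.063 and 0.144) and joint replicates 2 and 3 (adjusted p = 0.0513 and 0.107). It ended the ribosomal call for WEHS replicate 2 (adjusted p = 0.157) and joint replicate 3 (adjusted p = 0.145), and the cytokinin call for joint replicate 2 (adjusted p = 0.132).

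The sixth comparison tested whether the response to nitrate differs with and without WEHS. No transcript passed in limma (smallest adjusted p 0.912). At an unadjusted p below 0.05, 1777 (4.1%) did, under the share of 0.05 that arises by chance. For an1 the difference between the responses was -1.74 (SE 0.47, unadjusted p = 0.00264) and for d9 -0.38 (unadjusted p = 0.0209), and these 2 of the 4 gibberellin genes passed when adjusted over the list alone. The gibberellin list moved down (camera, adjusted p = 0.0272, and adjusted p = 0.657 with an estimated correlation). For nrt2.2 the interaction was -0.57 (unadjusted p = 0.168), for NAR2.1 -0.41 (unadjusted p = 0.144) and for NNR1 0.70 (unadjusted p = 0.278). At an unadjusted interaction p below 0.05 were 1 of the 81 transcripts called in both nitrate responses, 13 of the 107 called in nitrate against control and 61 of the 209 called in either. To be called in 1 response favours a difference between them. Over the 209 the median interaction was -0.12, and the smallest p adjusted over this set was 0.068. The 52 transcripts that fell beside WEHS, which were selected by that response, had a median interaction of -0.73, with 50 below 0.

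The 2 nitrate responses at 4 h, without and with WEHS, share no array. Across all 42976 transcripts, which are not independent replicates, they correlated at 0.438 (jackknife SD 0.385, range 0.235 to 0.6 when 1 array was left out) with a slope of 0.644, and 58.5% of transcripts went the same way. Among the 209 called in either, 205 went the same way and the correlation was 0.933. Of the rises, 78 were shared, where 0.31 arise by chance, and of the falls 3. The transcripts of sum1, gln1, NIR, TAZ1, Hb2, fnr1 and pgd3 are among the shared rises. All 103 transcripts raised by nitrate alone were above 0 beside WEHS, although only 78 passed there. The 2 responses to WEHS, without and with nitrate, correlated at -0.174 (jackknife SD 0.581), and 43.4% of transcripts went the same way. Leaving out 1 array gave -0.4 to 0.203, so that the sign is not settled.

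**Figure D4:**
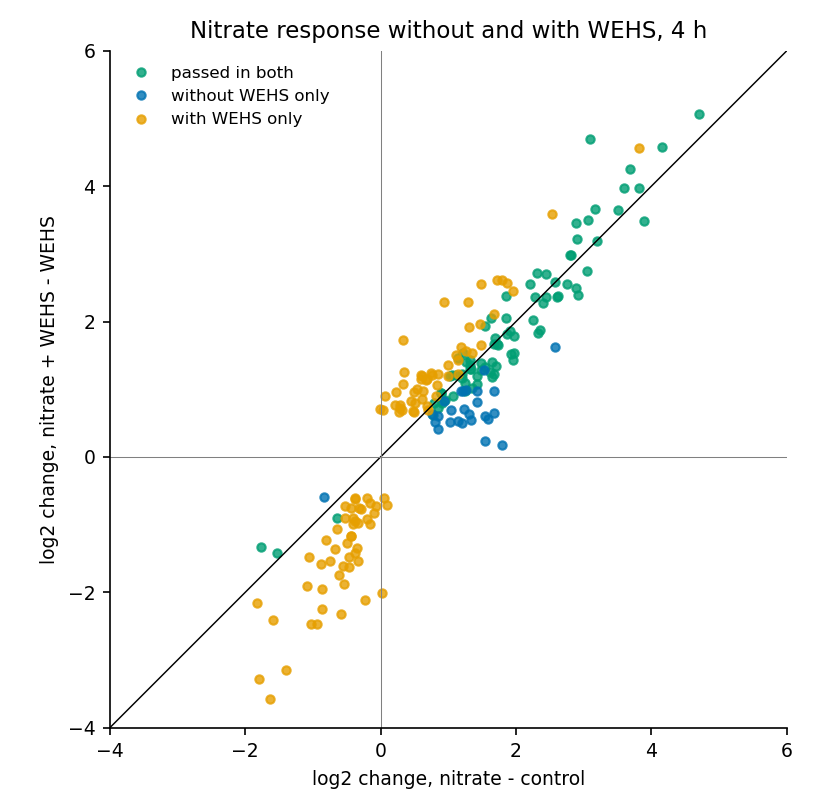
Log2 change with nitrate minus control (horizontal axis) against nitrate plus WEHS minus WEHS (vertical axis) for the 209 transcripts called in either, coloured by the comparison in which they passed, with the line of equal change. Of these, 205 lie on the same side of 0 in both.

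The seventh comparison set both additions at 8 h against the 4 h control, so that treatment, time and scan cannot be told apart in it. NIR, NAR, NNR1, sum1, gln1, TAZ1, HB34, Hb2, fnr1 and pgd3 were raised, as were the cytokinin oxidases CKX6, CKX8 and CKX12 and the response regulator RR4. The isoprenoid genes dxs2, psy2 and CCD8 and the potassium transporter HAK21 fell. In limma, 240 transcripts rose (197 genes, 33 named) and 207 fell (197 genes, 22 named), all without overlap of the groups, against 23.1% of all transcripts and 10% by chance. With 1 array left out there were 94 to 290 rises and 18 to 275 falls, and a fit to the 2 groups alone gave 61 and 11. Of the 103 transcripts raised by nitrate alone, 91 rose here and all were above 0, but both comparisons use the same control arrays, on which these transcripts were selected. Over all transcripts the 2 comparisons correlated at 0.305, where shared control arrays alone gave 0.507 in simulated data without change. The simulated transcripts were drawn independently, so that the spread of such a correlation between real arrays is not known from them.

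At 8 h NIR T04 rose by 4.86 (adjusted p = 0.00138), sum1 by 4.30 (adjusted p = 0.000467), NAR by 4.00 (adjusted p = 0.0401) and TAZ1 by 3.71 (adjusted p = 9.09e-06). HB34 rose by 3.28 in 1 of its 2 transcripts (adjusted p = 1.37e-06) and gln1 T03 by 3.08 (adjusted p = 0.000109). Hb2 rose by 2.97 (adjusted p = 1.73e-05) and the same pdh2 gene by 2.92 (adjusted p = 0.000411). NNR1 rose by 2.05 (adjusted p = 0.0466), fnr1 by 1.98 (adjusted p = 4.76e-06), pht9 by 1.68 (adjusted p = 0.0377), CKX6 by 1.28 (adjusted p = 0.00485), CKX8 by 1.19 (adjusted p = 0.0259), pgd3 by 1.18 (adjusted p = 0.000433), TPS7 by 1.12 (adjusted p = 0.00367), RR4 T03 by 1.02 (adjusted p = 0.00352), fgs1 by 0.77 (adjusted p = 0.00178) and the aquaporin pip2c by 0.71 (adjusted p = 0.0491). The brighter transcript of HB34 fell by 0.49 when adjusted over the list alone that its symbol matched. CKX12 rose from 10.58 ± 0.20 to 11.58 ± 0.35 (SD, adjusted p = 0.0267). dxs2 T02 fell by 2.61 (adjusted p = 0.0171), HAK21 fell by 2.00 (adjusted p = 0.0138), RIP fell by 1.98 (adjusted p = 0.049), CCD8 fell by 1.82 (adjusted p = 0.0495) and psy2 T02 fell by 1.43 (adjusted p = 0.0387). b-32 fell by 1.23 (adjusted p = 0.0351), NTGP5 fell by 1.20 (adjusted p = 0.00234), bHLH161 fell by 1.20 (adjusted p = 0.0389) and AUX6 fell by 0.63 (adjusted p = 0.0466). The number of arrays whose absence alone ended the call was 14 for pip2c, 13 for CCD8 and AUX6, 12 for NAR and NNR1, 11 for RIP, 10 for psy2 and bHLH161, 9 for pht9, 6 for b-32, 5 for CKX8 and CKX12, 4 for dxs2 and 1 for HAK21. Without a name, GRMZM2G127909 rose by 5.16 (adjusted p = 2.38e-08) and GRMZM2G399530 by 3.37 (adjusted p = 0.000129), while GRMZM2G455124 fell by 3.46 (adjusted p = 0.022) and GRMZM2G467893 fell by 3.04 (adjusted p = 0.00493).

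At 8 h pentose phosphate and ferredoxin moved up (adjusted p = 0.000142, and adjusted p = 0.359 with an estimated correlation), with 2 of 6 genes past the threshold and 3 adjusted over the list alone. Cytokinin moved up (adjusted p = 0.0197, and adjusted p = 0.684 with an estimated correlation). Of its 17 genes 4 rose, and adjusted over the list alone 4 rose and 3 fell, the response regulators RR8, RR9 and RR10. Nitrate reduction moved up (adjusted p = 0.0272, and adjusted p = 0.619 with an estimated correlation), with NNR1 as the 1 of its 4 genes that passed over all transcripts and adjusted over the list alone. The other members of this list carry the symbol CNX5, and NIR, NAR and sum1 are not in it. Leaving out 1 array ended the cytokinin call for control replicate 2 (adjusted p = 0.06) and 8 h replicate 1 (adjusted p = 0.0529), and that of nitrate reduction for control replicate 2 (adjusted p = 0.109) and 8 h replicate 3 (adjusted p = 0.0666).

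The last comparison set 8 h of both additions against 4 h. The clock gene GI, the regulators bZIP111 and ARF17, the transcript T01 of the response regulator RR4 and the methyltransferase MMT1 were higher at 8 h. The brighter RR4 transcript T03 did not pass here, even when adjusted over the cytokinin list alone. It lay 0.63 above control with both additions at 4 h and 1.02 above it at 8 h. The histone gene his2a1, the translation factors tif5A and eif3, the superoxide dismutase sod4 and the heat shock factor Hsf05 were lower. In limma, 1082 transcripts rose (1048 genes, 59 named) and 979 fell (908 genes, 69 named), all without overlap, against 35.5% of all transcripts and 10% by chance. The counts lay between 72 and 2285 rises and between 61 and 1687 falls when 1 array was left out, and of the genes named here only bZIP111 and GI passed whichever array was left out. Of the 1663 random probes, 14.4% differed at an unadjusted p below 0.05.

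From 4 h to 8 h, M2 rose by 4.35 (SE 1.01, adjusted p = 0.0347), bZIP111 T05 by 3.89 (SE 0.30, adjusted p = 0.000368), dcl4 by 3.37 (adjusted p = 0.0449), mbd115 by 2.91 (adjusted p = 0.0398), MMT1 by 2.86 (adjusted p = 0.0477), ARF17 by 2.49 (adjusted p = 0.0273), homeobox3 by 2.47 (adjusted p = 0.0467) and RR4 T01 by 2.33 (adjusted p = 0.0214). Of the falls, his2a1 fell from 9.75 ± 0.21 to 8.25 ± 0.32 (SD, adjusted p = 0.0335), MYBE1 fell by 1.41 (adjusted p = 0.0439), MZm3-3 fell by 1.37 (adjusted p = 0.0283), stv2 fell by 1.28 (adjusted p = 0.0391) and tif5A fell by 1.25 (adjusted p = 0.0241). The translation factor eif3 fell by 1.20 (adjusted p = 0.0291) and sod4 fell by 1.16 (adjusted p = 0.0324). Among list members, GI T06 rose from 13.72 ± 0.12 to 14.51 ± 0.05 (SD), by 0.80 (SE 0.11, adjusted p = 0.00751), the CNX5 gene GRMZM5G881641 rose by 1.32 (adjusted p = 0.0249), and FdI rose by 0.95 (adjusted p = 0.0395). EREB14 fell by 1.08 (adjusted p = 0.048), Hsf05 fell by 1.05 (adjusted p = 0.0474), rpl35 fell by 0.76 (adjusted p = 0.0359), TIFY30 fell by 0.58 (adjusted p = 0.046) and TPS5 fell by 0.58 (adjusted p = 0.0411). Without a name, GRMZM2G379913 rose by 5.70 (adjusted p = 0.0412) and GRMZM2G443447 by 4.79 (adjusted p = 0.0462), while GRMZM2G170602 fell by 2.83 (adjusted p = 0.0351) and GRMZM2G054221 fell by 2.31 (adjusted p = 0.0125).

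Between 4 h and 8 h, of the genes of nitrate transport and reduction, each by its brightest transcript, the CNX5 gene GRMZM5G881641 was the only 1 that passed. NIR (GRMZM2G079381) T05 differed by 0.00 (adjusted p = 0.998) and its T04 by 1.18, from 10.84 ± 1.05 to 12.02 ± 0.40 (SD, adjusted p = 0.232), NAR by 0.15 (adjusted p = 0.935), NNR1 by 0.14 (adjusted p = 0.88), nrt2.2 by -0.36 (adjusted p = 0.447) and NAR2.1 by 0.13 (adjusted p = 0.71). No list passed with camera or with the directional test of fry (smallest fry adjusted p 0.114). The lists that stand for shoot, seed, dividing cells and heat shock did not pass in any of the 8 comparisons, with smallest adjusted p of 0.599, 0.34, 0.64 and 0.313.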

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

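In this part, the tests of the place on the slide, of arrays held out, of the spread of the shares, of the other pairs of groups, of the signal over background and of the interaction by regrouping were chosen only after the result was seen, and the other tests were set before.

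The gibberellin genes are listed here because a test of the difference between their nitrate responses with and without WEHS passed (camera, adjusted p = 0.0272, 4 of 4 genes lower). The gibberellin list calls under WEHS and under nitrate beside WEHS use the same WEHS arrays, so these calls are not independent of it. On those arrays an1 averaged 13.49 against 12.29 in control, while D8, d9 and ga3ox2 were only 0.23, 0.18 and 0.15 higher. The difference was -1.74 for an1 and -0.38 for d9, and no single gene passed over all transcripts (smallest adjusted p 0.912). It is a weak result, since the adjusted p was 0.657 with an estimated correlation, 0.225 with fry and 0.16 with the random-probe axis as a covariate. The range over all alternatives, leaving out arrays included, was 0.00991 to 0.657. Leaving out 1 array ended the call for control replicate 2 (0.0553), nitrate replicate 2 (0.0821), WEHS replicates 2 (0.063) and 3 (0.128) and joint treatment replicate 3 (0.116). For single transcripts the real count was 0, so that 100 of 100 regroupings of the 12 arrays of 4 h had to give as many and the count tests nothing. The highest other regrouping gave 224 and points to a structure of the arrays that was not identified. It went with the second axis over all arrays at r = -0.70, yet another that did so at 0.70 gave 0.

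Random probes, which match no maize transcript and are in no comparison of the report, gave a signal. Between 8 h and 4 h of the joint treatment, 24 of 1663 differed in limma after adjustment and 14.4% at an unadjusted p below 0.05, against 2.5% for nitrate and 5.6% for WEHS against control. This bears on the 2061 transcripts that differ between these groups. A scan effect that shifts probes whatever RNA is on them was weighed first. The bound set before, more than 10% of random probes in 8 h against 4 h, was met at 14.4%, but it asked nothing of the other 3 comparisons that cross the scans. These gave 5.3% against control, 8.1% against nitrate and 13.7% against WEHS. The first lies 9.1 points under the 14.4% (jackknife SE 2.1) and the second 6.3 (SE 1.9), which goes against a scan effect alone, while the third goes with one. The third uses WEHS replicate 3, whose random probes stood apart, but how much of the 13.7% comes from that array was not determined. The third share ran from 9.7% to 14.9% with 1 array left out. The place of the arrays on the slide was weighed as well, since the 8 h arrays have the places of the control arrays and the share grows toward the far places. The joint treatment at 4 h against control has the same gap of places within 1 scan and gave 7.6%, which is 6.7 points lower (SE 1.9) and goes against place alone. With 3 arrays per group these errors are rough, and scan and place together stay open. Since place and treatment go together at 4 h, a real difference in RNA that reaches random probes stays open, as does the length of treatment, which has no control at 8 h.

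A single deviating array of the joint treatment at 4 h was weighed for the same 2061 transcripts. Without 1 of its 3 arrays as few as 252 remained past the threshold in number, which is under the bound set before for a deviating array, but that bound singled out no array, since leaving out 8 h replicate 2 gave fewer (72 rises and 61 falls). Then 1 array of 4 h and 1 of 8 h were held out together, and the 2061 transcripts with the smallest p without them were looked at in the held-out pair. No array is shared, so that no change gives 0% of the fold of the remaining arrays, as does a deviating array that stays in the fit. The 9 pairs showed 34.1% to 86.3% in the median. Over the pairs that leave a given array in the fit, the median was at least 65% for the 4 h arrays and at least 66.3% for the 8 h arrays, which argues against 1 deviating array as the source of the whole set. Single transcripts stay open. With 10 splits of the 6 arrays the share cannot fall under 0.1, and the real split gave 2061 and the highest other 137.

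Within groups the arrays spread along 1 main axis with 38.7% of the variance within groups. Its correlation over the 15 arrays, as deviations from group means, was computed for 7 measures, with permutation within groups. In size, Pearson's r was 0.58 for dividing cells (r = -0.58, permutation p = 0.124, rho = -0.61, permutation p = 0.053), 0.45 for shoot markers (rho = 0.41, permutation p = 0.195), 0.41 for ribosomal proteins (r = -0.41, rho = -0.52), 0.35 for the 95th percentile of the random probes (rho = -0.20), 0.3 for seed markers (rho = -0.45), 0.19 for heat shock genes (r = -0.19, rho = -0.09) and 0.16 for the first axis of the random probes (rho = -0.16). No adjusted p was below 0.469 for r or 0.275 for rho. Without the 2 farthest arrays r was -0.25 for dividing cells and 0.65 for shoot markers. With standard errors of 0.27 to 0.33 none of these can be ruled out, and the values under 0.4 that had been set as a bound against a cause do not decide either.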

How the results depend on the processing

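The offset of 50, the random-probe axis as a covariate, and the lists without or with changed members are tests chosen only after the result was seen, and all other alternatives were planned. No background correction, scaling to a common median and the deposited value table were not run, since the values are already normalized and the table holds the same ones, and a slide block could not be fitted. The 0 calls for WEHS, WEHS beside nitrate and the interaction stayed at 0 in every alternative but 1, the fall of 1 transcript under WEHS without WEHS replicate 1. Counts below are rises and falls, and where no reason is given the cause was not tested. With at least 1 log2 unit, falls were 2 for nitrate, 17 for the joint treatment and 32 for nitrate beside WEHS, and calls were 505 and 182 for 8 h against 4 h and 152 and 69 for 8 h against control. At an adjusted p of 0.01, calls were 68 and 1 for nitrate, 63 and 1 for the joint treatment, 62 and 12 for nitrate beside WEHS, 39 and 38 for 8 h against 4 h and 86 and 13 for 8 h against control, since both thresholds are stricter. Normexp background correction left 2 falls for nitrate. With no filter, falls were 21 for the joint treatment and 136 for 8 h against control, and with the filter on all 15 arrays, which tests fewer transcripts, 1 for nitrate and 17 for the joint treatment. The replicate block, which pairs arrays by number, gave 1703 rises for 8 h against 4 h. With only the arrays of the groups compared, calls were 35 and 0 for nitrate, 26 and 4 for the joint treatment, 45 and 8 for nitrate beside WEHS, 2557 and 1561 for 8 h against 4 h and 61 and 11 for 8 h against control. Array weights, which reached 5.14 for joint treatment replicate 1 and 4.7 for 8 h replicate 2, gave 177 and 23, 1556 and 2318, 2355 and 2862, 7018 and 9870, and 2845 and 3672 in the same order. The random-probe axis as a covariate gave 71 and 8 for nitrate beside WEHS, 1692 rises for 8 h against 4 h and 126 falls for 8 h against control. The correlation of the 2 nitrate responses was 0.438 over all transcripts and 0.933 over those called.

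Leaving out 1 array gave 70 to 117 rises and 1 to 8 falls for nitrate, 0 to 0 rises and 0 to 1 falls for WEHS, 70 to 139 and 1 to 49 for the joint treatment, 0 for WEHS beside nitrate and the interaction, 64 to 172 and 11 to 162 for nitrate beside WEHS, 72 to 2285 and 61 to 1687 for 8 h against 4 h, and 94 to 290 and 18 to 275 for 8 h against control. The correlations ran from 0.235 to 0.6 for the nitrate responses and from -0.4 to 0.203 for the WEHS responses. Arrays that moved a count by more than 1.5 times, with the rises and falls without them, were for 8 h against 4 h control 3 (684, 694), nitrate 2 (1853, 1344), WEHS 1 (2285, 1687), joint treatment 1 (344, 335), 2 (150, 151) and 3 (130, 122), and 8 h 1 (77, 65), 2 (72, 61) and 3 (237, 367). For nitrate beside WEHS they were nitrate 1 (120, 34), WEHS 1 (172, 162), 2 (73, 11) and 3 (64, 11), joint treatment 1 (69, 29), 2 (67, 19) and 3 (92, 33), and 8 h 1 (104, 29) and 2 (92, 24). For the joint treatment they were control 2 (70, 3) and 3 (75, 1), nitrate 1 (105, 17) and 3 (101, 18), WEHS 2 (97, 13) and 3 (101, 19), joint treatment 1 (74, 22), 2 (85, 6) and 3 (82, 9), and 8 h 1 (90, 8), 2 (90, 10) and 3 (105, 13). For 8 h against control they were control 2 (156, 108) and 3 (102, 23), nitrate 1 (188, 117), WEHS 2 (198, 136), joint treatment 1 (189, 116) and 3 (200, 128), and 8 h 1 (102, 22), 2 (94, 18) and 3 (157, 131).

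Of 130 named calls, from 116 (no filter) to 130 (array weights, offset of 50) passed in the other alternatives, except 70 with only the groups compared, 98 with the random-probe covariate and 65 of the 65 still tested with the filter on all arrays, and none changed direction. Over the 15 fits that leave out an array, 1448 of 1950 calls were kept. In nitrate against control, sum1, gln1, TAZ1, Hb2, HB34, pdh2, GLK52, fnr1, pgd3, fgs1 and TPS7 passed whichever array was left out. Of 14 list calls, 0 held with the estimated correlation, 7 with fry, 9 with the random-probe covariate, 10 with the filter on all arrays, 11 with all transcripts of a gene or array weights, 12 with the replicate block, 13 with only the groups compared and 14 in the rest. Of lists not called, 15 passed with all transcripts of a gene, 8 with added members, 5 each with array weights and the offset of 50, and up to 4 in each other setting over all arrays. Pentose phosphate and ferredoxin kept all its calls when 1 array was left out, as did cytokinin in the joint treatment. The other list calls each ended without 1 to 7 arrays. The cell division list, not called under WEHS, reversed its direction and passed without control replicate 1 (0.0362), and the cause was not tested. Signal over background limits all of this, since 16780 transcripts did not exceed the random probes on 3 arrays.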

Other observations

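In this part, the splits for WEHS and for WEHS beside nitrate, the comparisons of pairs of groups beyond the 8 planned and the clock list with changed members were tests chosen only after the result was seen, and the other tests were set before.

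The 4 h arrays of nitrate alone and the 8 h arrays of the joint treatment differed in 1 transcript past the threshold in limma, although 5886 (13.7%) differed at an unadjusted p below 0.05. That transcript is T05 of bZIP111, 3.12 higher at 8 h (adjusted p = 0.0051). WEHS against nitrate at 4 h gave 20 rises and 117 falls, and 8 h against WEHS 501 rises and 658 falls.

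With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 107 transcripts for nitrate (highest other 1), 159 for the joint treatment (highest other 1), 183 for nitrate beside WEHS (highest other 0) and 447 for 8 h against control (highest other 5), and in each 1 of 10 splits gave as many. For WEHS and for WEHS beside nitrate the real count was 0, so that 10 of 10 splits had to give as many (highest other 0) and the count tests nothing.

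The time of day may contribute to the differences between 8 h and 4 h, a hypothesis set before the test. The largest difference of a clock gene was 0.80 in GI (adjusted p = 0.00751), 0.8 in size, while gigz1b differed by 0.62 (adjusted p = 0.07) and PRR59 by 0.58 (adjusted p = 0.146). At 4 h, GI with both additions was already lower than control (-0.39) and lower than with WEHS alone (-0.38). Both differences passed only when adjusted over the list alone. Against the 4 h control, the 8 h arrays differed by 0.41 in GI, 0.66 in gigz1b and 0.61 in PRR59. Part of the 0.80 in GI thus lies in the low level of the joint treatment at 4 h. There is no 8 h control, so the response of these genes to the treatment itself at 8 h stays open. The circadian clock list as fixed has 7 measured genes, of which 4 are another kind of gene by their symbols. It did not pass in camera (adjusted p = 0.347 in 8 h against 4 h and 0.198 in 8 h against control). It passed with all transcripts of a gene (adjusted p = 0.0236 and 0.0272), as planned, although transcripts of 1 gene are not independent. It also passed when reduced to the other 3 members after the data had been seen (adjusted p = 0.00813 in each). Neither was run with an estimated correlation.

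A decline of the nitrate response by 8 h was tested on the 79 genes that rose under nitrate alone. Their median change from 4 h to 8 h was 0.02, at percentile 96.6 of 10000 random lists of like brightness, of which the middle 90% lay between -0.13 and 0.01. Relative to such lists this argues against a decline of these genes as a set, while 2 of their transcripts fell and 5 rose. There is no 8 h control and 8 h has its own scan, so a decline hidden by a change with time or scan stays open. Over all 42976 transcripts, which are not independent replicates, the nitrate response and the change from 4 h to 8 h correlated at -0.339. They share no array, and simulated data without change gave 0.012. The simulated transcripts were drawn independently, without the axes along which the arrays vary together. No spread was computed for the -0.339, and the jackknife SDs of the correlations of the nitrate and of the WEHS responses were 0.385 and 0.581. Whether it differs from 0 is therefore not settled.

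The isoprenoid and carotenoid genes that fell with nitrate beside WEHS may respond to nitrate in general, not only where WEHS is present, a hypothesis set before the test. The genes were grouped after their falls in that comparison were seen, and tested in nitrate against control, which shares no array with it. In it 6 of 6 were below 0, with CCD8 at -1.83, dxs2 at -1.39, psy2 at -1.09, an1 at -0.58, Hds1 at -0.16 and dxr at -0.03. So were 49 of all 52 transcripts that fell with nitrate beside WEHS, so that 6 of 6 does not set these genes apart. None of the 6 genes passed by itself (adjusted p 0.129 for CCD8, 0.357 for psy2), and their interaction with WEHS did not pass either (adjusted p 0.912 to 0.943). All 6 interactions were negative (-0.31 to -1.75), and all 6 genes were higher under WEHS alone (0.47 to 1.20, none past the threshold). Of the 52 transcripts that fell with nitrate beside WEHS, 50 were above 0 under WEHS alone and 50 below 0 in the interaction. Both share the WEHS arrays with the comparison that selected them, so that a response to WEHS as a part of these falls stays open.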
